A study of Mus musculus with 12 samples.

How the data were processed

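The measured quantity was the abundance of RNA per gene in 12 libraries of mouse embryonic stem cells, 3 in each of 4 groups named by the labels as wild type and Bod1l knockout with and without etoposide. Per the labels, RNA was extracted with Trizol, passed through poly(A) selection and ribosomal RNA removal, fragmented, and made into strand-specific paired-end libraries. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.6 and cutadapt 3.4, aligned with HISAT2 2.2.1 to GRCm39 and quantified with StringTie 2.2.1. Per the file headers, the deposited TPM values were computed by the authors for each gene with StringTie, scaled by gene length and to a fixed total within each library. Per the file headers, the deposited FPKM values were computed by the authors in the same step, scaled by gene length and by the number of mapped fragments but not to a fixed total. Per the file headers, the deposited coverage values are the mean read depth over each gene that the authors' StringTie step reported, with no scaling by library size. The values analysed here are not read counts, so no count model was used. Whether the counting used the strand of the reads is not stated.

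The tables held 41079 gene IDs in every library, and the few entries that shared an ID were summed. The 14107 genes with a mean TPM of at least 1 over the 12 libraries were kept. Values were taken as log2(TPM + 1), and limma was fitted with 4 group means and 5 comparisons, the last being the difference of the etoposide change between genotypes. Its moderated variances used a trend on abundance (prior degrees of freedom 3.91, residual 8). P values were adjusted by Benjamini-Hochberg within each comparison, and an adjusted p under 0.05 was called a change. The labels call the replicates biological but do not describe separate cultures, so the p values measure the spread between these libraries. Gene lists for DNA repair pathways, p53 targets, cell states, the cell cycle, stress and metabolism were fixed before the data were examined. They were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 32 lists that had at least 5 tested members. None of the 13 names in the list of mitochondrially encoded genes was found in the tables, so that list was not tested. No gene of the mitochondrial genome stood above 0 in any library.

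Depth was worked out from the ratio of coverage to FPKM shared by about 27% of the genes, which gives aligned bases rather than a number of reads. Mean depth was 6.88 ± 0.37 gigabases in untreated wild type, 6.53 ± 0.66 in treated wild type, 5.87 ± 0.64 in the untreated knockout and 7.28 ± 0.44 in the treated knockout (± SD, n = 3). Replicates correlated at r = 0.994 to 0.996 across genes, which are not independent replicates. The median SE of a comparison was 0.139 on the log2 scale for genes of mean TPM 1 to 5, 0.067 for 5 to 50 and 0.037 above that.

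The code was tested on simulated data with 50 genes planted at each size of change. In the untreated comparison of genotypes it recovered 40% of planted changes of 0.25, 72% of 0.5, 96% of 1 and 100% of 2 on the log2 scale, with 6 false calls. For the interaction the shares were 24%, 60%, 82% and 96%, with 5 false calls. The planted genes were a small part of the 14107 simulated, against 7000 called in the real untreated comparison of genotypes. The adjustment was therefore stricter in the simulation, and its shares need not describe comparisons in which many genes changed.

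The genes named were Bod1l, the 10 highest and 10 lowest changes of each comparison between groups and the 5 highest and 5 lowest of the interaction. Apart from Bod1l, these had to pass the test, and clone, model and pseudogene names were left out. In the comparisons between groups, though not in the interaction, every library of one compared group also had to lie above every library of the other. From each list described, up to 4 members with the lowest adjusted p were also available. A few genes that the rule names are not reported here. Genes named outside this rule are said in the text to be chosen after their values were seen. The alternatives were a pseudocount of 0.1, other filters on low values, FPKM, median-of-ratios and quantile scaling, the replicate number as a block, fits on the compared groups alone, a robust spread, leaving out each library, and for lists an estimated correlation and the rotation test fry. Transcript structure, strand and the deleted part of Bod1l were not examined, since the tables hold a single value per gene. The FPKM alternative kept the filter at 1 and the pseudocount at 1, while a TPM value was 2.65 to 2.75 times its FPKM value, so the filter kept fewer genes, 12031, and the pseudocount shrank low values more. The computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1.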

Results

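RNA was sequenced from mouse embryonic stem cells, pluripotent cells grown from the early embryo, in 12 paired-end libraries. Wild-type cells and cells labelled as a Bod1l knockout were each left untreated or treated with etoposide, a drug that traps topoisomerase II on cut DNA and so causes double-strand breaks. Each of the 4 groups held 3 libraries labelled as biological replicates. Bod1l encodes a subunit of the SETD1A complex, which methylates lysine 4 of histone H3, and the title of the series names the expression of DNA damage repair genes as the subject. The labels name tamoxifen for the knockout libraries alone, so the effects of the knockout and of tamoxifen were not separable in any comparison of genotypes. The aligned bases per library, worked out from the coverage and FPKM columns, were 7.30, 6.69 and 6.64 gigabases in untreated wild type, 5.78, 7.04 and 6.77 in treated wild type, 6.51, 5.87 and 5.23 in the untreated knockout and 7.76, 6.88 and 7.20 in the treated knockout. Expression is given as TPM (mean ± SD, n = 3 libraries per group), and changes as differences of log2(TPM + 1) ± SE, a scale that understates the change of genes with low values.

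Bod1l itself separated the genotypes in every library. It stood at 48.5, 48.8 and 50.6 TPM in the untreated wild-type libraries and at 46.5, 51.1 and 48.6 in the treated ones, against 12.0, 11.2 and 11.5 in the untreated knockout and 12.95, 12.4 and 11.8 in the treated knockout. The gene lies on chromosome 5 from 41944881 to 42001695 (GRCm39). The mean of 11.6 ± 0.415 TPM in the untreated knockout was 23.5% of the wild-type mean of 49.3 ± 1.13, and the treated knockout held 25.3% of the treated wild-type level. The log2 change was −2.0 ± 0.05 without etoposide (limma with Benjamini-Hochberg adjustment, adjusted p = 1.68e-10) and −1.90 ± 0.05 with it (adjusted p = 2.37e-10). Etoposide left no detectable change in Bod1l in wild type (−0.02 ± 0.05, limma adjusted p = 0.827). The labels do not say which part of the gene was removed, so the remaining signal cannot be assigned to transcripts inside or outside the deletion.

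The first comparison set the untreated knockout against untreated wild type. Homologous recombination and mismatch repair genes were lower in the knockout, while p53 target genes and genes of the 2-cell-like state were higher. Rad50, a part of the MRN complex that senses broken DNA ends, fell from 35.3 ± 2.16 to 7.86 ± 0.404 TPM. Plk2, a p53-induced kinase, rose from 32.1 ± 1.41 to 82.4 ± 1.67 TPM. Lefty1 and Lefty2, secreted inhibitors of Nodal signalling, fell from 36.8 ± 0.461 to 4.61 ± 0.374 and from 137.8 ± 7.25 to 31.3 ± 1.68 TPM.

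Of the 163 DNA repair and checkpoint genes tested, 75 were lower, 29 were higher and 59 did not pass the test. The counts were 76 and 31 when adjusted over the list alone. The list ranked lower than the other genes, with a median change of −0.08 (camera, the gene list test of limma, adjusted p = 1.09e-05). Homologous recombination genes had 21 members lower and 4 higher of 37, and 21 and 5 when adjusted over the list alone (camera adjusted p = 2.45e-05). Besides Rad50 (−2.03 ± 0.05, chromosome 11 from 53540346 to 53598146), this group held Rad51c (−1.61 ± 0.06), Mcm8 (−1.37 ± 0.05) and Fignl1 (−0.82 ± 0.04), each with a limma adjusted p of at most 7.29e-09. Mcm8 is a helicase used in recombination. Mismatch repair genes had 11 lower and 3 higher of 21 (camera adjusted p = 0.0072), among them Mlh3 (−0.94 ± 0.05). Base excision genes had 10 lower and 3 higher of 24 (camera adjusted p = 0.0221). This call did not hold with the members' correlation taken from the data (adjusted p = 0.0804 with an estimated correlation). The base excision genes that fell included Apex1 (−0.44 ± 0.03), the main abasic site endonuclease, and Neil2 (−1.24 ± 0.11), while the scaffold Xrcc1 rose (0.37 ± 0.03). Checkpoint genes had 11 lower and 3 higher of 22, among them the kinase Atr (−1.13 ± 0.07) and the adaptor Mdc1 (−0.55 ± 0.03), with a camera adjusted p of 0.0072 (adjusted p = 0.108 with an estimated correlation). Counts adjusted over the list alone were equal to these for mismatch repair, base excision and checkpoint genes.

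The remaining repair pathways did not pass as lists in the main setting. Fanconi anemia genes had 10 lower and 5 higher of 25 (camera adjusted p = 0.0584), with Fancd2 (−0.84 ± 0.03) among those that fell. That list passed without the filter on low values (adjusted p = 0.0151), with median-of-ratios scaling (0.048) and without replicate 1 of the untreated knockout (0.0399). End-joining genes had 9 lower and 6 higher of 26 (camera adjusted p = 0.0926, and 0.0253 without the filter), including lower Xrcc5, which encodes Ku80 (−0.93 ± 0.03), and Prkdc, the DNA-dependent protein kinase (−0.78 ± 0.05). Nucleotide excision genes had 6 lower and 8 higher of 21 (camera adjusted p = 0.971), with Gtf2h3 and Gtf2h4 of the TFIIH complex lower (−0.81 ± 0.04 and −0.67 ± 0.05).

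**Figure D1:**
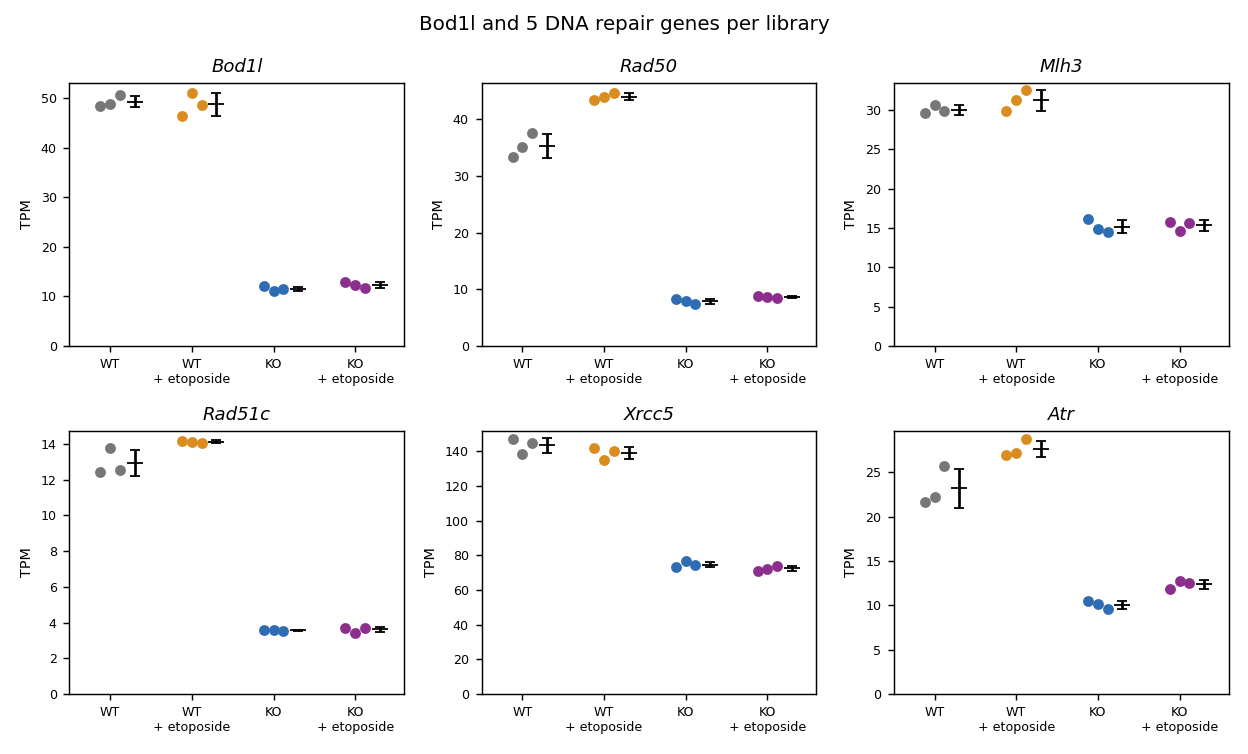
TPM of Bod1l and 5 DNA repair genes (vertical axes, starting at 0) in each of the 12 libraries, grouped by genotype and treatment, with the group mean ± SD (n = 3) beside the points. In each panel the 6 knockout libraries lie below the 6 wild-type libraries, as for Rad50 with group means of 35.3 and 44.0 TPM in wild type and 7.86 and 8.64 TPM in the knockout.

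Of 41 p53 target genes, 34 were higher and 1 was lower in the untreated knockout, or 36 and 1 when adjusted over the list alone (median 0.44, camera adjusted p = 4.01e-12). Plk2 (1.34 ± 0.04), Trp53inp1 (0.92 ± 0.04), Btg2 (0.85 ± 0.03) and Mdm2, the ubiquitin ligase that degrades p53 (0.84 ± 0.03), led the list, with limma adjusted p values of at most 4.5e-09. The member that fell was Rrm2b (−0.44 ± 0.06), picked out after its values were seen. Intrinsic apoptosis genes went both ways, with 6 higher and 6 lower of 18 (camera adjusted p = 0.814). All 15 tested genes of the 2-cell-like state, a rare condition of stem cell cultures that resembles the early cleavage embryo, were higher (median 1.74, camera adjusted p = 2.53e-09). The list held 27 names, of which 22 were in the tables and 15 passed the filter on low values. That filter uses the mean over all 12 libraries, so members low in wild type could pass through the knockout libraries. This favours higher members in the count, the median and the test. Zscan4d rose from 1.24 ± 0.427 to 11.2 ± 1.18 TPM and Eif1ad8 from 1.24 ± 0.314 to 11.9 ± 1.03. Most of these genes have near-identical copies that share reads, so values of single members of the Zscan4, Tcstv, Usp17l and Eif1ad families are uncertain.

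Glycolysis and hypoxia genes were lower, with 16 of 19 below wild type and none above, or 18 and none when adjusted over the list alone (median −0.42, camera adjusted p = 5.61e-09, and adjusted p = 0.159 with an estimated correlation). Ldha fell by 0.83 ± 0.04, from 1033 ± 28.2 to 579.6 ± 20 TPM, and Pgk1 changed by −0.59 ± 0.04. S phase and replication genes had 16 lower and 2 higher of 29, or 17 and 2 when adjusted over the list alone (camera adjusted p = 0.00113), including Ccne1 (−0.33 ± 0.02) and Mcm6 (−0.27 ± 0.02). The integrated and unfolded protein stress response had 14 higher and 2 lower of 20 (camera adjusted p = 0.00489), led in size by the transcription factor Ddit3 (0.98 ± 0.10) and by Ddit4 (0.89 ± 0.07), which is also a p53 target in the list above. Imprinted genes had 10 higher and 1 lower of 22 (camera adjusted p = 0.00544, and adjusted p = 0.108 with an estimated correlation), with Peg10 at 0.99 ± 0.04 and Mest at 0.63 ± 0.05.

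Of the lists for cell states, extraembryonic endoderm genes had 6 higher and none lower of 11, among them the basement membrane genes Lama1 (0.61 ± 0.04) and Col4a1 (0.63 ± 0.05), at a camera adjusted p of 0.0236 (adjusted p = 0.319 with an estimated correlation). That call also ended with FPKM in place of TPM (adjusted p = 0.0789) and without the filter on low values (adjusted p = 0.0614). Naive pluripotency genes had 8 lower and 3 higher of 25 (camera adjusted p = 0.224), with Utf1 (−0.71 ± 0.04) and Lin28a (−0.54 ± 0.04) among the lower. Primed pluripotency genes had 5 lower and 2 higher of 13 (camera adjusted p = 0.113, and 0.0488 without the filter), including the DNA methyltransferases Dnmt3a (−0.72 ± 0.06) and Dnmt3b (−0.31 ± 0.03). Primitive streak genes had 4 higher, with Nodal at 0.44 ± 0.03, and 3 lower, with Lefty1 and Lefty2, of 15 (camera adjusted p = 0.971). Genes of the SETD1 complex and its relatives had 8 lower and 3 higher of 23, Bod1l included, or 7 and 3 when adjusted over the list alone (camera adjusted p = 0.343). Neuroectoderm, trophectoderm and feeder fibroblast markers did not pass (camera adjusted p = 0.602, 0.656 and 0.971). The feeder list had 3 higher and 2 lower of 7, and Vim, among the lower, fell by 0.52 ± 0.02. The list of oestrogen receptor targets, fixed because tamoxifen binds that receptor, had 2 higher and 4 lower of 8 (camera adjusted p = 0.585). Median, mean and test differed in sign for the nucleotide excision, apoptosis, SETD1, naive pluripotency, primitive streak, trophectoderm, feeder, G2/M and germline lists, none of which passed.

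Across all 14107 genes tested, 7000 differed between untreated knockout and wild type, 3961 higher and 3039 lower. The share of higher calls, 56.6%, was 48.7% with median-of-ratios scaling, so the direction of the balance rested on the scaling. It was 49.1% with FPKM, where the same filter and pseudocount weigh more on low values and 12031 genes were tested. At a change of 1.5-fold or more there were 590 higher and 759 lower genes, and at 2-fold or more 119 and 200. The 1.5-fold counts were 938 higher and 922 lower with a pseudocount of 0.1, so that balance rested on the pseudocount. With FPKM they were 244 and 555. The lowest named genes included Lefty1 (−2.75 ± 0.07, chromosome 1 from 180762587 to 180765966), Hsf2bp, a meiotic recombination factor (−2.61 ± 0.14), Cbr4 (−2.33 ± 0.09), Ccdc191 (−2.31 ± 0.11), Ercc6l2 (−2.21 ± 0.08), Gatb (−2.19 ± 0.09), Alg8 (−2.18 ± 0.09), Lefty2 (−2.10 ± 0.07) and Ndufa4l2 (−2.04 ± 0.31). The highest were Tcstv2b (2.87 ± 0.17), Usp17lb, the linker histone H1f2 (2.60 ± 0.10, from 3.92 ± 0.546 to 28.7 ± 1.38 TPM), Eif1ad7, Eif1ad8, Eif1ad3, Zscan4d, Zscan4a, Eif4a3l1 and Tcstv2c (2.35 ± 0.17), nearly all from multicopy families.

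The second comparison set the knockout against wild type in the presence of etoposide. DNA repair genes were again lower and 2-cell-like genes higher, and the excess of p53 target genes was present with a smaller median. Rad50 stood at 44.0 ± 0.584 TPM in treated wild type and 8.64 ± 0.160 in the treated knockout (−2.22 ± 0.05, limma adjusted p = 1.03e-10). In all, 6228 genes differed, 3168 higher and 3060 lower (50.9% higher, against 45.8% with FPKM and 56.5% with quantile normalization), with 295 and 797 at 1.5-fold or more and 73 and 241 at 2-fold or more. The 1.5-fold counts were 458 higher and 972 lower with a pseudocount of 0.1, and 96 and 561 with FPKM.

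Of the 163 repair and checkpoint genes, 81 were lower and 28 higher, or 82 and 30 when adjusted over the list alone (median −0.13, camera adjusted p = 6.08e-06). Homologous recombination genes had 24 lower and 4 higher of 37 (camera adjusted p = 4.35e-06), with Rad51c at −1.71 ± 0.06 and Mcm8 at −1.36 ± 0.05. Fanconi anemia genes had 14 lower and 7 higher of 25, with Fan1 at −0.84 ± 0.07 (camera adjusted p = 0.0422, and adjusted p = 0.227 with an estimated correlation), a call that ended with FPKM (adjusted p = 0.0588). Mismatch repair genes had 8 lower and 3 higher of 21 (camera adjusted p = 0.0157, and adjusted p = 0.0665 with an estimated correlation), with Mlh3 at −0.98 ± 0.05. Checkpoint genes had 11 lower and 2 higher of 22 (camera adjusted p = 0.00778, and adjusted p = 0.116 with an estimated correlation). Rad9b, a checkpoint clamp subunit, was among the 10 lowest genes of the comparison (−2.06 ± 0.16). The end-joining, base excision and nucleotide excision lists did not pass (camera adjusted p = 0.0604, 0.0504 and 0.985). End-joining genes passed without the filter on low values (adjusted p = 0.0112) and without replicate 1 of treated wild type (0.0323). Base excision genes passed without the filter (0.00889), with a pseudocount of 0.1 (0.0494), and without replicate 1 of treated wild type (0.0452) or replicates 1 or 2 of the treated knockout (0.0442 and 0.0477).

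The p53 targets had 25 higher and 1 lower of 41, or 28 and 1 when adjusted over the list alone (median 0.18, camera adjusted p = 4.66e-06), with Plk2 at 0.47 ± 0.04 and Mdm2 at 0.43 ± 0.03. All 15 2-cell-like genes that passed the filter were higher (median 1.67, camera adjusted p = 2.14e-11), with the same limit of the filter as in untreated cells. Replication-dependent histone genes had 13 higher and none lower of 25 (median 0.60, camera adjusted p = 0.000363), with H1f2 at 2.58 ± 0.10 and H2bc4 at 1.63 ± 0.16. These genes share sequence with their relatives, and their transcripts mostly lack poly(A) tails, so poly(A) selection recovers them poorly. In the untreated cells the histone list had 9 higher and none lower (camera adjusted p = 0.0756), and it passed without the filter (0.0488), with median-of-ratios scaling (0.0294), and without replicate 2 of untreated wild type (0.0374) or of the untreated knockout (0.0346). S phase genes had 14 lower and 1 higher of 29 (camera adjusted p = 0.00157) and the stress response 12 higher and 1 lower of 20 (camera adjusted p = 0.00289). Glycolysis genes had 18 lower and none higher of 19, with Ldha at −0.78 ± 0.04 (camera adjusted p = 8.23e-09, and adjusted p = 0.135 with an estimated correlation). Imprinted genes had 9 higher and none lower of 22 (camera adjusted p = 0.00205, and adjusted p = 0.0785 with an estimated correlation). G2/M genes had 15 higher and 3 lower of 26, with Hmmr at 0.49 ± 0.04 and Aurka at 0.18 ± 0.02 (camera adjusted p = 0.00466, and adjusted p = 0.128 with an estimated correlation). Cytosolic ribosomal protein genes had 20 higher and 3 lower of 48, by a median of 0.04 (camera adjusted p = 0.033, and adjusted p = 0.514 with an estimated correlation). Adjusted over the list alone, the counts higher and lower were 8 and 14 for Fanconi anemia, 3 and 12 for checkpoint, 2 and 15 for S phase, 13 and 1 for stress response, 0 and 19 for glycolysis and 16 and 3 for G2/M genes, and equal to those above for the other lists. The ribosomal call ended with FPKM (adjusted p = 0.223), with median-of-ratios scaling (0.0621), and without replicate 2 of treated wild type (0.165) or replicates 1 or 3 of the treated knockout (0.0529 and 0.0538).

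Lefty1 (−3.01 ± 0.07), Cbr4 (−2.66 ± 0.09), Hsf2bp (−2.63 ± 0.14) and Lefty2 (−2.37 ± 0.07) were the lowest named genes under etoposide, and Ccdc191, Rad50, Alg8, Gatb and Rad9b were among those that came next. Tcstv2b (3.00 ± 0.17), Tcstv2c (2.77 ± 0.17), Eif1ad8 (2.73 ± 0.12) and Zscan4d (2.60 ± 0.14) were the highest, followed by Eif1ad3, H1f2, Zscan4a, Eif4a3l1, Eif1ad7 and Tcstv1b. The naive pluripotency, primed pluripotency, primitive streak, extraembryonic endoderm, neuroectoderm, trophectoderm, feeder, SETD1 and oestrogen receptor lists did not pass (camera adjusted p from 0.17 to 0.985). Median, mean and test differed in sign for the nucleotide excision, SETD1, naive pluripotency, primitive streak, trophectoderm, feeder and oestrogen receptor lists.

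The knockout effects under both conditions, which share no library, overlapped in 2555 higher and 2468 lower genes, where independent lists of these lengths would share 889.5 and 659.2. Only 16 genes were called in opposite directions. Across genes, which are not independent replicates, the log2 changes correlated with r = 0.854.

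The third comparison, etoposide against no treatment in wild type, measured the response to the drug. The p53 target genes rose together, while the DNA repair genes as a list did not differ detectably from the other genes. Plk2 rose from 32.1 ± 1.41 to 123.9 ± 2.18 TPM and Mdm2 from 114.2 ± 0.866 to 269.6 ± 9.24. Tap1, a peptide transporter of antigen presentation, rose from 1.62 ± 0.0249 to 14.5 ± 0.363 TPM. Nanog fell by 0.18 ± 0.02 on the log2 scale, from 776.6 ± 8.37 to 685.2 ± 12.2 TPM.

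Of 41 p53 targets, 33 were higher and 1 lower, or 33 and 2 when adjusted over the list alone (median 0.90, camera adjusted p = 8.27e-23). Plk2 (1.92 ± 0.04), Btg2 (1.75 ± 0.03), Trp73 (1.73 ± 0.05) and Trp53inp1 (1.36 ± 0.04) had the lowest limma adjusted p values of the list, at most 1.05e-10. Tigar was the member that fell (−0.35 ± 0.07), picked out after its values were seen. The apoptosis genes Pmaip1 (1.40 ± 0.09), Bbc3 (1.27 ± 0.06) and Apaf1 (1.19 ± 0.05) rose, but the apoptosis list, with 6 higher and 2 lower of 18, did not pass (camera adjusted p = 0.245). Immediate early genes had 8 higher and 1 lower of 15, led by Fosl1 (1.96 ± 0.13) and Fos (1.22 ± 0.14), at a camera adjusted p of 0.0329 (adjusted p = 0.332 with an estimated correlation). DNA repair and checkpoint genes had 35 higher, 19 lower and 109 not past the test, with the same 35 and 19 as counts adjusted over the list alone (median 0.02, camera adjusted p = 0.937). Xrcc1 (0.57 ± 0.03), Shld2 of the shieldin complex (0.72 ± 0.06) and Ercc5 (1.07 ± 0.11) rose. None of the pathway lists of DNA repair passed (camera adjusted p from 0.215 to 0.967). Fry, the rotation test in limma that does not compare a list with other genes, called all repair genes together (adjusted p = 0.00237). It also called each pathway list but checkpoint genes (fry adjusted p = 0.151). Homologous recombination (fry adjusted p = 0.000824), end-joining (0.00372), nucleotide excision (0.0103), base excision (0.0353) and Fanconi anemia (0.0385) genes were higher by fry, and mismatch repair genes (0.0284) lower.

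Naive pluripotency genes had 14 lower and 1 higher of 25, or 15 and 1 when adjusted over the list alone, with Lin28a at −0.51 ± 0.04 and Sall4 at −0.28 ± 0.03 (median −0.15, camera adjusted p = 3.09e-06, and adjusted p = 0.126 with an estimated correlation). G2/M genes had 12 lower and 1 higher of 26, with the mitotic kinases Plk1 at −0.41 ± 0.04 and Aurka at −0.20 ± 0.02 (camera adjusted p = 0.000134, and adjusted p = 0.126 with an estimated correlation). SETD1 complex genes and their relatives had 7 lower and none higher of 23, such as Wdr5 at −0.20 ± 0.03 (camera adjusted p = 0.00187, and adjusted p = 0.0577 with an estimated correlation). S phase genes had 10 lower and 4 higher of 29 (camera adjusted p = 0.0386), glycolysis genes 4 lower and none higher of 19 (0.0296) and cytosolic ribosomal protein genes 10 higher and 1 lower of 48 (0.0408). With an estimated correlation these 3 lists had adjusted p = 0.212, 0.597 and 0.597. Adjusted over the list alone, the counts higher and lower were 2 and 14 for G2/M, 8 and 2 for immediate early and 6 and 0 for ribosomal protein genes, and equal to those above for SETD1, S phase and glycolysis genes. The S phase call ended without replicate 1 or 2 of untreated wild type (0.0565 and 0.0537) or replicate 2 of treated wild type (0.0803). The glycolysis call ended without replicate 2 or 3 of untreated wild type (0.0537 and 0.0561) or replicate 2 of treated wild type (0.243), and the immediate early call without replicate 1 of treated wild type (0.0768). The ribosomal call ended without replicate 2 or 3 of untreated wild type (0.125 and 0.11) or replicate 1 or 3 of treated wild type (0.165 and 0.0799), and its median turned to −0.01 with median-of-ratios scaling. FPKM ended the S phase, glycolysis, immediate early and ribosomal calls (0.0727, 0.0759, 0.235 and 0.307). Primed pluripotency, primitive streak, extraembryonic endoderm, neuroectoderm, trophectoderm, 2-cell-like and feeder lists did not pass (camera adjusted p from 0.0775 to 0.739), although the primed list passed without the filter (0.018). Median, mean and test differed in sign for the Fanconi anemia, base excision, apoptosis, neuroectoderm, 2-cell-like, oestrogen receptor, interferon, stress response and imprinted lists, none of which passed.

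Etoposide changed 4841 genes in wild type, 2937 higher and 1904 lower, so that 60.7% of the calls were higher. That share was 45.5% with median-of-ratios scaling and 43.9% with quantile normalization, so the balance of small changes rested on the scaling. The larger changes were mostly upward, with 894 higher and 49 lower genes at 1.5-fold or more and 353 and 0 at 2-fold or more. Tap1 (2.56 ± 0.09), the adhesion gene Nectin4 (2.46 ± 0.09), Dusp13b (2.44 ± 0.19), Ano7 and Nkx2-9 were the highest named genes, followed by Plcd4, Anxa8, Ltb4r1, Sec14l5 and Sytl1. The lowest were Mir7651 (−0.99 ± 0.26), Etv1 (−0.87 ± 0.16), Gsc (−0.86 ± 0.14), Vax2, Mir6918, Gpha2, Mir485, Emp1 (−0.80 ± 0.08), H2ac12 and AF357426. Values of the microRNA genes and of others that overlap a neighbour are uncertain, since the sources used here do not state whether the counting used strand.

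**Figure D2:**
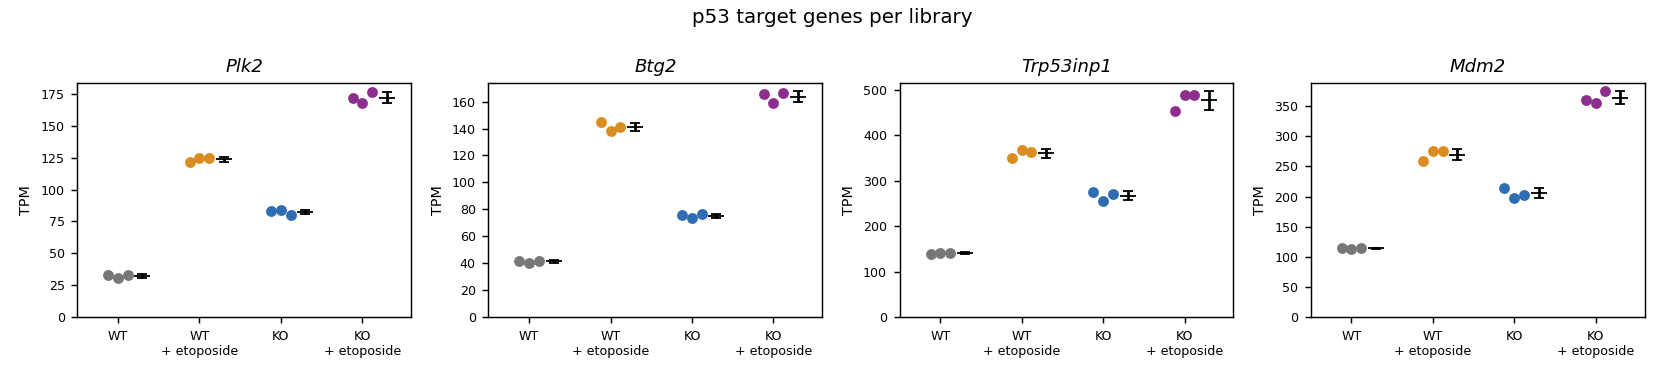
TPM of 4 p53 target genes (vertical axes, starting at 0) in each of the 12 libraries, grouped by genotype and treatment, with the group mean ± SD (n = 3) beside the points. Plk2 had group means of 32.1 TPM in untreated wild type, 123.9 in treated wild type, 82.4 in the untreated knockout and 172.3 in the treated knockout, and the other genes show the same order of groups.

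The fourth comparison, etoposide against no treatment in the knockout, gave the same leading list. Of 41 p53 targets, 33 rose and none fell, or 34 and none when adjusted over the list alone (median 0.58, camera adjusted p = 8.22e-26), with Trp73 at 1.48 ± 0.05, Btg2 at 1.12 ± 0.03, Plk2 at 1.06 ± 0.04 and Mdm2 at 0.82 ± 0.03. Plk2 reached 172.3 ± 4.20 TPM in the treated knockout. Naive pluripotency genes had 14 lower and 1 higher of 25, with Sall4 at −0.25 ± 0.03 (camera adjusted p = 2.32e-05, and adjusted p = 0.229 with an estimated correlation). SETD1 complex genes had 8 lower and none higher of 23, with Wdr5 at −0.14 ± 0.03 (camera adjusted p = 0.00226, and adjusted p = 0.0623 with an estimated correlation). Immediate early genes had 6 higher and none lower of 15, with Fosl1 at 1.66 ± 0.13 (camera adjusted p = 0.0107, and adjusted p = 0.252 with an estimated correlation), and FPKM ended that call (adjusted p = 0.105). Cytosolic ribosomal protein genes had 15 higher and none lower of 48 by a median of 0.04 (camera adjusted p = 0.00149, and adjusted p = 0.504 with an estimated correlation), a call that median-of-ratios scaling ended (adjusted p = 0.0653). Adjusted over the list alone, 9 SETD1 complex genes were lower and 7 immediate early genes higher, and the naive pluripotency and ribosomal counts stayed equal.

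DNA repair and checkpoint genes had 19 higher and 15 lower of 163 in the treated knockout, or 17 and 14 when adjusted over the list alone (camera adjusted p = 0.962), with Xrcc1 at 0.42 ± 0.03 and Shld2 at 0.59 ± 0.06. Bod1l stood at 0.09 ± 0.05 (limma adjusted p = 0.222). The pathway lists of DNA repair, the markers of other cell states and the remaining lists did not pass (camera adjusted p from 0.0524 to 0.962). Of the repair lists, fry in limma called homologous recombination alone (adjusted p = 0.0427), against 0.104 for all repair genes. S phase genes, with 10 lower and 2 higher of 29, passed without the filter (adjusted p = 0.00612), with median-of-ratios scaling (0.0415), and without replicate 1 of the untreated knockout (0.0374) or replicates 1 or 3 of the treated knockout (0.0438 and 0.031). Without the filter the apoptosis (0.0317), glycolysis (0.0321) and stress response (0.0226) lists passed too, the first 2 also without replicate 1 of the untreated knockout (0.0374 each). Median, mean and test differed in sign for all repair genes together and for the Fanconi anemia, checkpoint, neuroectoderm, 2-cell-like, histone, interferon, stress response and germline lists. In total 3525 genes changed, 2041 higher and 1484 lower. The share of higher calls, 57.9%, was 50.3% with median-of-ratios scaling and 49.2% with quantile normalization. At 1.5-fold or more there were 519 higher and 16 lower genes, and at 2-fold or more 122 and 4. The highest named genes were Ppp1r36 (1.69 ± 0.13), Fosl1, Nkx2-9, P2rx6, Tap1 (1.48 ± 0.09), Trp73, Kcnj4, Prr15l, Ano7 and Dusp13b. Commd5 had the lowest value (−2.26 ± 0.25), followed by Prcd, Mir6943, Kiss1, the signalling ligand Bmp4 (−0.67 ± 0.10), Zic5, Spic, Fgf10, Msc and Mpped2. The responses in wild type and knockout, which share no library, had 1810 higher and 1100 lower genes in common, where independent lists would share 424.9 and 200.3, and 3 genes moved in opposite directions (r = 0.785 across genes).

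**Figure D3:**
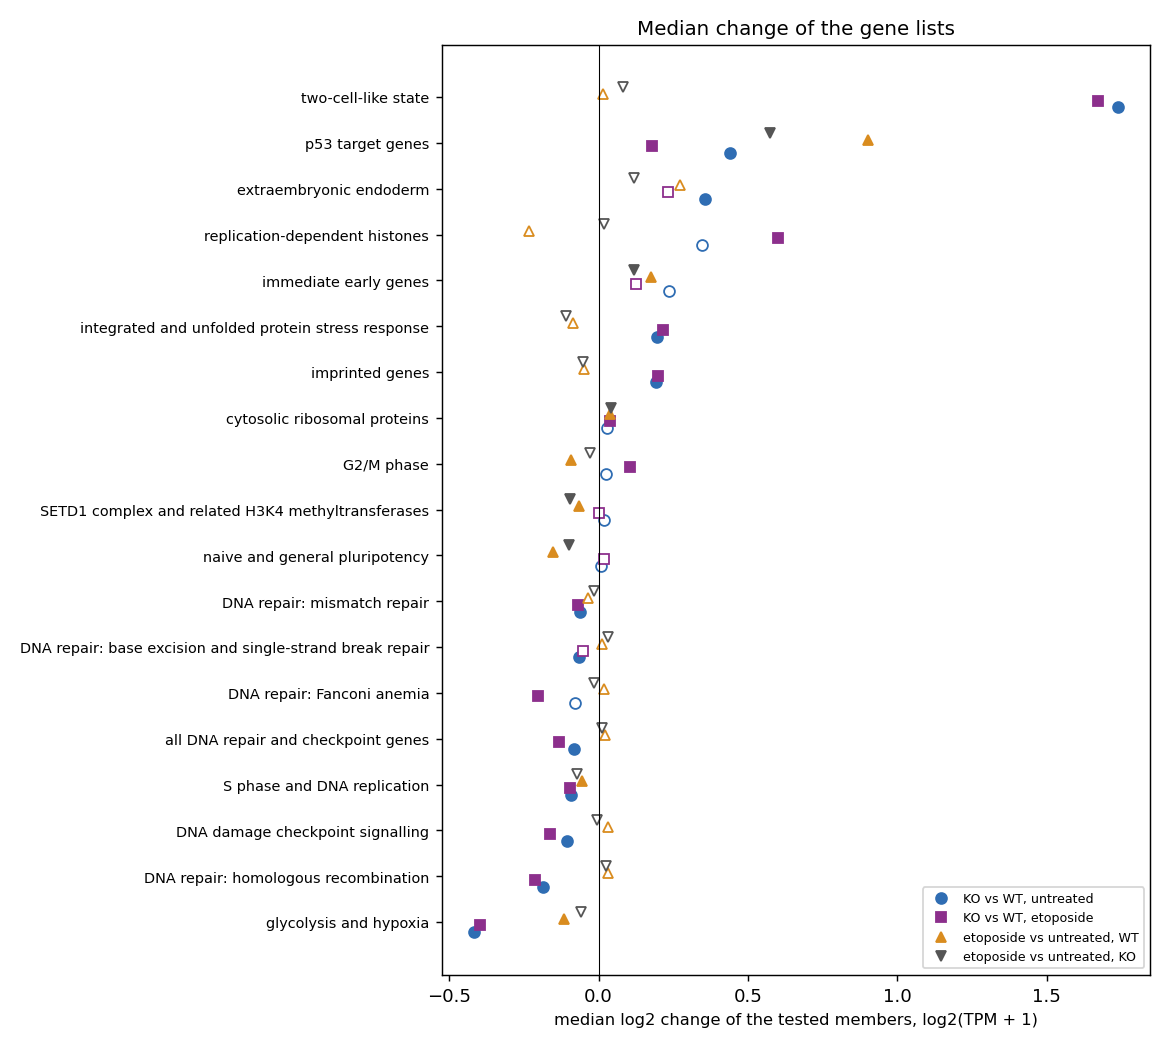
Median log2 change (horizontal axis, log2(TPM + 1) scale) of the tested members of each gene list that passed camera in at least 1 of the 4 comparisons between groups. Filled symbols mark comparisons in which the list passed. The 2-cell-like list lies at 1.74 and 1.67 in the comparisons of genotypes, and the p53 list at 0.90 and 0.58 in the comparisons of treatment.

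The last comparison tested whether etoposide changed genes by a different amount in the knockout than in wild type. The p53 targets rose less on the log2 scale in the knockout, from a higher starting level, and no DNA repair gene passed the test. The difference of the etoposide change, knockout minus wild type, was −0.86 ± 0.05 for Plk2 (limma adjusted p = 9.8e-06), −0.64 ± 0.04 for Btg2 (3.83e-05), −0.77 ± 0.08 for Ephx1 (0.000555) and −0.52 ± 0.05 for Trp53inp1 (0.00047). Of 41 p53 targets, 15 had a smaller change in the knockout and none a larger one, or 30 and 1 when adjusted over the list alone (median −0.30, camera adjusted p = 5.79e-24). Of the 163 repair and checkpoint genes none passed, over all genes or over the list alone (camera adjusted p = 0.997), with Xrcc1 at −0.16 ± 0.04 (limma adjusted p = 0.157) and Xrcc6 at −0.14 ± 0.04 (0.226). G2/M genes had none past the test over all genes and 8 with a higher value adjusted over the list alone (median 0.07, camera adjusted p = 1.53e-10), with Plk1 at 0.23 ± 0.06 (limma adjusted p = 0.0839). Replication-dependent histone genes had a median of 0.20 (camera adjusted p = 0.00274, and adjusted p = 0.167 with an estimated correlation), naive pluripotency genes 0.03 (0.00742, and adjusted p = 0.661 with an estimated correlation) and extraembryonic endoderm genes −0.14 (0.0184, and adjusted p = 0.661 with an estimated correlation), with no single member past the test in these 3 lists. FPKM ended the histone call (adjusted p = 0.119) and leaving out replicate 3 of the treated knockout ended the naive pluripotency call (0.0685). The extraembryonic endoderm call ended without replicate 1 or 2 of untreated wild type (0.0521 and 0.119), replicate 1 of treated wild type (0.0521), replicate 3 of the untreated knockout (0.0537) or replicates 1 or 3 of the treated knockout (0.0821 and 0.0622). Median, mean and test differed in sign for several lists that did not pass, among them all repair genes together and the nucleotide excision, base excision, checkpoint, apoptosis and S phase lists. The ribosomal protein list, at an adjusted p of 0.312, passed with median-of-ratios scaling (0.0012) and without replicate 1 of treated wild type (0.0365) or replicate 2 of the treated knockout (0.0284). The glycolysis list, also at 0.312, passed without replicate 1 of untreated wild type (0.0355), replicates 1 or 3 of treated wild type (0.0168 and 0.0492) or replicate 3 of the untreated knockout (0.0307).

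In total 174 genes passed the interaction test, 10 with a larger value in the knockout and 164 with a smaller one, of 1604 at an unadjusted p under 0.05. The lowest values belonged to Commd5 (−1.90 ± 0.36), Mir7083 (−1.38 ± 0.30), Plcd4 (−1.15 ± 0.20), Nectin4 (−1.09 ± 0.12) and Tap1 (−1.08 ± 0.13), and the highest to Prxl2b (0.42 ± 0.09), Rbm14 (0.36 ± 0.05), Atad2b (0.34 ± 0.06), Gemin7 (0.24 ± 0.05) and Calcoco2 (0.23 ± 0.04). The calls of Commd5, Mir7083, Prxl2b, Atad2b and Gemin7 ended when single libraries were left out, and that of Plcd4 ended without the filter on low values (limma adjusted p = 0.0623). With camera and an estimated correlation, the calls that held were all repair genes together, homologous recombination, mismatch repair, p53 targets, 2-cell-like, S phase and stress response genes in the untreated comparison of genotypes. Under etoposide they were all repair genes, homologous recombination, p53 targets, 2-cell-like, S phase, stress response and histone genes. The p53 targets alone held in each comparison of treatment, and the p53 targets and G2/M genes in the interaction.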

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

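The tests of TPM increments (over members and over libraries), scaling, depth, a fixed share, tamoxifen and shared reads (single genes and family totals) were chosen only after the results were seen, while those of splits of libraries and of RNA of treated cells were written down before their own results were seen. The etoposide change differed between knockout and wild type in 174 genes. By list, the median difference, knockout minus wild type, was −0.301 for p53 targets, 0.030 for naive pluripotency, −0.144 for extraembryonic endoderm, 0.068 for G2/M and 0.203 for replication-dependent histone genes. The lowest single values were those of Commd5 (−1.899), Mir7083 (−1.382), Plcd4 (−1.153), Nectin4 (−1.091) and Tap1 (−1.082), and the highest those of Prxl2b (0.424), Rbm14 (0.357), Atad2b (0.335), Gemin7 (0.237) and Calcoco2 (0.231). Among p53, apoptosis and stress response genes, Plk2 stood at −0.863, Btg2 at −0.635, Trp53inp1 at −0.521, Ephx1 at −0.772, Apaf1 at −0.505, Bbc3 at −0.395 and Ddit4 at −0.567. Of 100 splits of the libraries into mixed groups, only the true one, 1 of the 100, gave as many as 174 genes, and the highest of the others gave 2. The 5 lists past the test were matched or exceeded in 7 of the 100 splits, the true one included, with up to 7 lists, so this count did not exclude chance for the number of lists. Mixed splits keep part of the interaction, which also widens the spread within mixed groups, so their gene and list counts do not measure variation between libraries alone.

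The smaller log2 rise of p53 targets in the treated knockout was weighed against 2 plain explanations. If the drug added the same number of transcripts to a raised baseline, the ratio of the TPM increments would be 1, and its median over the 33 members that rose in wild type was 0.882, with a bootstrap 95% interval of 0.757 to 0.908 from 10000 resamplings of members. Over libraries, a jackknife gave an SE of 0.035 and an interval of 0.801 to 0.963, and the 34 members chosen by their mean rise in both genotypes gave 0.883 (0.810 to 0.955). Over the list, equal increments therefore do not account for all of the difference. The ratio was under 1 in 30 of the 33 members. Among the genes named for the interaction it was 0.979 for Plk2, 0.953 for Trp53inp1, 0.888 for Btg2 and 0.714 for Ephx1. For Plk2 and Trp53inp1 the increments were thus nearly equal in both genotypes, and their smaller log2 rise lay mostly in the raised baseline. With median-of-ratios scaling the list median was −0.27 (camera in limma, adjusted p = 1.23e-22), so scaling between libraries does not account for the smaller rise of the list.

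The higher p53 targets in the untreated knockout could in part be RNA of treated cells within those libraries. Genes that etoposide lowered in wild type had a median change of −0.128 in the untreated knockout, with a standard error of 0.0162 over genes. This lay on the side of the cut set beforehand that such RNA would give, but too near the cut to call. The comparison also shares its wild-type libraries, so that explanation stays undecided. A single fixed share of such RNA as the whole cause is argued against by 14 of 28 members whose needed share lay over 3 standard errors from the median of 44.7%. Depth differed in the opposite direction under etoposide, where the p53 median was still 0.179, so depth is unlikely to be the cause. Tamoxifen was named for the knockout alone, with no wild-type library labelled with it, so tamoxifen and the knockout cannot be told apart here. The oestrogen receptor targets had a camera adjusted p of 0.585 (limma), which cannot decide this without such a library.

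For the 2-cell-like genes, reads shared between near-identical copies could inflate a rise. Arg2, Tmem92 and Zfp352, which were chosen after their values were seen as members outside the large multicopy families, rose by a median of 1.211 in a fit without the filter, from 0.282, 0.437 and 0.208 to 1.5, 3.99 and 1.81 TPM, too near the floor to decide. Reads moved between copies leave the total of a family as it was. Families were taken by the start of the gene name. The totals over all copies were higher in the untreated knockout in 5 families. Zscan4 rose from 3.38 ± 0.754 to 30.2 ± 2.72 TPM (± SD, n = 3), Tcstv from 8.12 ± 1.17 to 71.4 ± 5.75 and Usp17l from 1.65 ± 0.318 to 20.5 ± 2.3. Tdpoz rose from 0.937 ± 0.0619 to 7.54 ± 0.17 and Eif1ad, by a smaller factor, from 86.2 ± 1.2 to 136 ± 5.01. These totals argue against such moves as the whole cause there, less firmly for Tdpoz, which started near the floor. The Pramel family was set apart after its total was seen, which changed by −0.167 over 58 copies that are not all alike, so for Pramel6 and Pramel7 shared reads stay open.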

How the results depend on the processing

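With camera and an estimated correlation, 7, 7, 1, 1 and 2 lists passed in the 5 comparisons in the order of the report, against 12, 14, 8, 5 and 5 at the preset correlation, while fry, which tests each list without reference to other genes, passed 27, 28, 23, 9 and 3. In some lists fry took the direction opposite to that of camera. It called primitive streak genes lower (median 0.215) in the untreated comparison of genotypes and nucleotide excision genes lower (0.045) in the treated one. Fry called Fanconi anemia (0.017), base excision (0.010) and primitive streak (−0.153) genes higher under etoposide in wild type. Median-of-ratios scaling turned the ribosomal median there to −0.011. The 174 interaction genes became 104 without the filter on low values, 102 with quantile normalization and 93 to 131 when single libraries were left out. Leaving out single libraries gave 5 to 7 lists for etoposide in wild type, 5 to 8 in the knockout and 3 to 6 for the interaction, and ranges for genes in the other comparisons stayed within 1.5 times the full result. FPKM gave 4 lists for etoposide in wild type, and dropping the filter gave 10 in the knockout. At a 1.5-fold change or more, the overlap of the knockout effects fell from 5023 to 820 genes and that of the etoposide effects from 2910 to 484. Over the named genes, 8961 of 9282 values stayed called or stayed not called, 312 lost a call and 9 gained one. None that was called in either setting turned, while values called in neither were counted as kept whatever their sign. The labels give groups the same replicate numbers, and correlations between libraries of equal number ran from −0.045 to 0.045, with 5 of 12 libraries correlating best with their own number, so the numbers were not taken as pairs. A replicate block gave 6901, 6068, 4702, 3391 and 122 genes. No alternative turned the direction of a gene called both there and in the main setting, and the cause of these differences was not tested.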

Other observations

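The tests of mitochondrial families, of gene position and of shared controls were chosen only after the results were seen. Nuclear genes named for mitochondrial translation and for complex I of respiration were lower in the untreated knockout. Of 78 mitochondrial ribosomal proteins (Mrpl and Mrps), 43 were lower and 5 higher, by a median of −0.14 (camera in limma, Benjamini-Hochberg adjusted over 4 families, adjusted p = 2.12e-09, and adjusted p = 0.000302 with an estimated correlation). The mitochondrial aminoacyl-tRNA synthetases had 13 lower and 2 higher of 17, with Ears2 at −1.40 and Iars2 at −1.33 (limma camera adjusted p = 1.03e-05, and adjusted p = 0.00235 with an estimated correlation). Genes named as complex I subunits and assembly factors (Nduf) had 26 lower and 8 higher of 50 (limma camera adjusted p = 0.000133, and adjusted p = 0.00733 with an estimated correlation). This family was taken by name alone and includes Ndufa4l2 (−2.04), so its members need not all belong to complex I. Cytochrome c oxidase subunits, a family defined here without assembly factors, had 8 higher and 0 lower of 14, at a limma camera adjusted p of 0.0332 (adjusted p = 0.228 with an estimated correlation). The oxidase assembly factor Cox15, picked out after its value was seen, fell by 1.05, so the families of complex I and of the oxidase are not compared like for like. The first 3 families were lower under etoposide too, and etoposide itself moved none of the 4 past the test in either genotype. The scaling did not change these directions.

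Of the 200 genes at least 2-fold lower in the untreated knockout, 58, or 29.0%, had a tested neighbour starting head to head within 1 kb or overlapping by up to 200 bases, against 11.2% on average in 10000 sets of genes matched for expression (one-sided permutation p = 1.0e-04, the smallest these draws can give). The 58 genes had a median change of −1.22 and their neighbours 0.01, with 18 neighbours lower, 19 higher and none changed 2-fold in the same direction. Under etoposide 67 of 241 genes had such a neighbour (27.8%), with 20 neighbours lower, 14 higher and 4 changed 2-fold in the same direction. The genes were chosen for their fall and the neighbours were not. Untreated neighbours near the median of all genes, 0.04, could thus arise without a one-sided effect. Of all 14107 genes, 49.6% were called in the untreated comparison and only 200 were 2-fold lower, so few such neighbours were awaited. Ccdc191 fell by 2.31 beside Qtrt2 at 0.12, and Mcm8 fell by 1.37 beside Trmt6 at 0.12, pairs chosen after their values were seen. Among genes at least 2-fold higher the share was 5.0% (6 of 119), against 9.7% on average in sets matched to those genes. That share showed no excess (one-sided permutation p = 0.979). One hypothesis is that losing Bod1l, or tamoxifen, lowers output mostly from a single side of shared promoters, which could be tested with strand-specific nascent RNA and H3K4 trimethylation at these starts. Because the use of strand in the counting is not stated, reads crossing between overlapping first exons may add to the pattern of 29.0%.

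The changes in the untreated knockout and under etoposide in wild type covaried across genes by 0.0402, where simulations of unchanged groups that share the wild-type libraries gave 0.00775 on average and 0.00909 at most in 100 runs, so the shared controls are unlikely to produce all of the covariance. The correlation across genes, which are not independent replicates, was r = 0.326, under the simulated 0.498, a measure that real effects of each kind lower by adding variance. The overlap of 1570 higher and 688 lower genes, where independent lists would share 824.7 and 410.2, with 692 in opposite directions, may come in part from those shared controls. The 3 libraries were not divided, since each part would not keep 2 of them, and 20 simulations of unchanged groups on shared libraries gave 0 genes higher in both and 0 lower in both, which leaves out how shared controls act on genes with real effects. A fresh set of untreated wild-type cultures, with tamoxifen given to both genotypes, would separate these effects.

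Splits of the libraries were compared with the true grouping for each comparison. With only 10 splits per comparison between groups, a share under 0.05 cannot be reached. The true grouping alone, 1 of 10 splits, gave the highest number of genes in each, with 7000, 6228, 4841 and 3525 genes against at most 1, 0, 0 and 1 in the others. For lists the true grouping gave 12, 14, 8 and 5 against at most 9, 13, 8 and 3, a number reached by 3 of 10 splits, the true one included, for etoposide in wild type and by the true one alone elsewhere. The other splits put 2 libraries of one group with 1 of the other and so keep part of the real difference. That difference also widens the spread within the mixed groups, which by itself pushes their gene counts towards none. These splits therefore do not measure how many genes unchanged groups would give.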
